A study of Paralichthys olivaceus with 18 samples.

How the data were processed

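Spleens of 10-month-old Japanese flounder were sampled at 6, 12 and 24 h after an intramuscular injection of 200 µl of a V. anguillarum suspension in PBS (group V, infected) or of PBS (group C, control), per the labels' protocols. The series' design text states that 3 individual fish were used per group and time, so the 18 libraries are separate animals. Total RNA was extracted with Trizol and small RNA libraries were made with the NEBNext Multiplex Small RNA kit, per the labels' protocols. fastp 0.12.4 and Bowtie 1.1.2 are named in the submitters' processing notes, with no role or parameters. The genome build, the miRNA reference, the length and quality filters and the counting rule are not given in the sources used here.

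The deposited values are whole-number counts of reads per mature miRNA, 1 column per library, not normalized, as the values themselves show: they sum to a different total in each library. Columns were matched to samples by their names, and no column was left unused. No value of 1 occurs in the table, whose smallest value above 0 is 2 (1767 values), and 42.4% of the values are 0, so that a listed 0 can stand for a count under 2. No fold is given against a group whose 3 libraries are all listed at 0. Where 1 or 2 libraries of a group are listed at 0, the size of the fitted fold change is uncertain. This holds for miR-11987-x and miR-11980-x in the 24 h controls and for miR-9-y and n020-3p in the infected fish at 24 h. 362 of the 1218 miRNAs had a count in every library. The table holds 68 groups of miRNAs with identical values in all libraries (316 miRNAs). In 34 of the groups (229 miRNAs) the values summed to 6 counts or fewer per miRNA, where equal values can be a coincidence. Of the other 34 groups (87 miRNAs), 10 pairs were tested (20 miRNAs, at least 64 counts each), and their equal values point to reads counted under several names. miRNAs that differ only in a letter, copy or species name can share reads in this way, and their values are uncertain. No reference genome or miRNA sequences were used, so no position or sequence is given for any miRNA.

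Totals per library, replicates 1 to 3, were 11690592, 12000659 and 12972569 for infected and 14633799, 16367987 and 14193808 for control fish at 6 h. They were 12606951, 11121672 and 12404957 against 15373795, 16167343 and 15078646 at 12 h, and 11696864, 11509053 and 6615484 against 13050279, 14379333 and 14217222 at 24 h. Replicate libraries of a group differed by far more than counting error, with a chi-square per degree of freedom of 278 to 2904 over the pairs, so that all 18 were kept as separate replicates. Sequencing adapters without molecular identifiers count PCR copies, and no identifier is mentioned in the labels. The precision of the comparisons is set by the spread between fish: the common biological coefficient of variation was 48.9%.

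Counts were analysed with edgeR 4.0.16 in R 4.3.3. miRNAs were filtered with filterByExpr by group (minimum count of 10), which left 499, libraries were scaled with TMM factors, and a quasi-likelihood model with 1 coefficient per group was fitted to all 18 libraries (glmQLFit with robust estimation, glmQLFTest, two-sided), so that the 6 groups share 1 estimate of the spread. The Benjamini-Hochberg adjustment ran over all miRNAs tested in a contrast, with a threshold of 0.05. Contrasts were infected against control at 6, 12 and 24 h, their mean, a joint test of the 3, the differences of the infection effect between times with their joint test, and time within controls and within infected fish. The standard error of a log2 fold change is the size of the unshrunken fold change divided by the square root of F. The fold changes given are those that edgeR shrinks slightly with a prior count. The shrunken and unshrunken values can therefore differ for miRNAs with few counts. CPM (counts-per-million) values are scaled by the TMM factors and are given as mean ± SD, except single values of 12 h control libraries, which are not TMM-scaled. Measures of library composition were compared with exact two-sided permutation tests of 3 against 3 libraries, whose smallest p is 0.1, and by permutation within times over all 3 times.

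There were 29 lists of miRNA families, 16 by family or response and 13 of cell type or neighbouring tissue markers, matched by family number, and the 22 with at least 3 measured members were tested with limma 3.58.1 (camera, preset correlation of 0.01) on log2 CPM with a prior count of 2, with adjustment over the lists. The number of members past the threshold is given over all miRNAs tested and adjusted over the list alone. The groups, the designs, the lists, most alternatives and the rule for named miRNAs were set before the data were examined. The rule named the 10 miRNAs with the smallest p per direction among those past the threshold at each time, 5 per direction for the averaged effect and the differences between times, and 5 for time in controls and in infected fish. It also named the most abundant member of miR-155, miR-146, miR-21, miR-223, miR-142, miR-150, miR-462, miR-731, miR-451, miR-144, miR-122, miR-1, miR-133, miR-216, miR-375, miR-192, miR-126, miR-143 and miR-210, up to 4 members per list with the smallest p, and the 10 most abundant miRNAs.

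Alternatives were RLE and upper-quartile factors, scaling by total count only, no filter, a strict filter (10 CPM in 3 libraries), DESeq2 1.42.0, limma voom, no robust estimation, a fit of the compared groups only, the replicate number as a block, each library left out in turn, a log2 fold change above 1 in addition to the threshold, entries summed by family and arm (with the suffix x read as 5p and y as 3p, which is an assumption), and the most abundant miRNA left out. For the lists, an estimated correlation and the fry test were added. Counting identical entries once, thinning every library to the total of the shallowest and leaving out the numbered candidates were chosen after seeing the data. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

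The tests were tested on simulated data with the real means and library sizes and with known changes. At 6, 12 and 24 h they recovered 12.2%, 19.4% and 19.4% of miRNAs changed by a fold of 2. Of those changed by a fold of 4 they recovered 55.6%, 63.8% and 54.2%. The simulated miRNAs tested were 529, 515 and 510, with 2 false calls in each. Among them, 98, 98 and 98 had been changed by a fold of 2 and 99, 94 and 96 by a fold of 4. The real comparisons gave 9, 19 and 48 calls. The adjustment is more lenient where many miRNAs change. These shares of recovered miRNAs and false calls therefore cannot be carried over to the real comparisons. With the list of miR-17/92 changed by a fold of 2 at 24 h, camera called that list (adjusted p 2.26e-13) and 0 of the other lists among the 22 tested. This simulation took the means and library sizes from the real data. In the real libraries, the estimated correlation between list members ranged from −0.0508 (lymphoid) to 0.876 (intestine or kidney epithelium). Other splits of the real libraries gave up to 5, 6 and 2 lists at 6, 12 and 24 h. The simulation therefore cannot tell how often camera with its preset correlation calls a list falsely in the real data.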

Results

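MicroRNAs were measured by small RNA sequencing in the spleen of Japanese flounder (Paralichthys olivaceus), a marine flatfish, after an intramuscular injection of Vibrio anguillarum, a bacterium that causes vibriosis in fish, or of PBS. Spleens were taken at 6, 12 and 24 h after injection, from 3 infected and 3 PBS-injected fish at each time, which gives 6 groups and 18 libraries, with 1 individual fish per library. The question, as the series title puts it in substance, is how the miRNA profile responds to the infection and how the response depends on time. The table lists 1218 miRNAs. Of these, 34 carry a flounder name (prefix pol-miR or pol-let), 706 are named after miRNAs of other species, and 478 are numbered candidates (pol-miR-n followed by a number, shortened below to n and the number). The names after other species end in x, y or z, and the meaning of this suffix is not given in the sources used here. The named miRNAs of other species held 85.1% of all counts, the flounder names 14.6% and the numbered candidates 0.298%.

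The most abundant miRNA was miR-146-x, a miRNA known to dampen Toll-like receptor signalling, with a mean of 10.4% of the counts over the 18 libraries. It was followed by miR-26-x (9.80%), miR-143-y (8.54%), which is typical of smooth muscle, and miR-126-y (7.81%), which is typical of endothelium. Next came miR-100-x (6.86%), the erythroid pol-miR-144-3p (5.23%), miR-181-x (4.98%), pol-miR-21-5p (4.63%), miR-125-x (4.02%) and the erythroid miR-451-x (3.80%). The share of miR-146-x was 10.2% ± 0.964 in infected and 4.52% ± 2.62 in control spleens at 6 h (mean ± SD, n = 3 fish per group). It was 13.6% ± 0.790 and 5.64% ± 0.736 at 12 h, and 23.6% ± 1.97 and 4.56% ± 0.253 at 24 h. Control 6 h replicate 3 stood apart from the other controls of its time, with 7.54% of its counts in miR-146-x against 3.22% and 2.81%. Together, the 10 most abundant miRNAs held 63.8% of the counts in infected and 60.6% in control spleens at 6 h, 67.6% and 65.0% at 12 h, and 74.3% and 64.8% at 24 h. At each time the exact two-sided permutation p of these shares was 0.1, the smallest that 3 fish against 3 allow. Over the 3 times, permuted within times, it was 0.00025 for both measures, the smallest that this test allows. With the 10 most abundant chosen within each library, the shares at 6 h were 64.8% and 63.7% (exact two-sided permutation p = 0.2), a difference of 1.18 points in place of 3.19.

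Library totals ranged from 6615484 counts in infected 24 h replicate 3 to 16367987 in control 6 h replicate 2. Infected libraries held fewer counts than controls at every time. In mega-counts (M), the mean was 12.2 ± 0.669 M against 15.1 ± 1.15 M at 6 h, 12.0 ± 0.806 M against 15.5 ± 0.563 M at 12 h, and 9.94 ± 2.88 M against 13.9 ± 0.725 M at 24 h (SD, n = 3). The exact two-sided permutation p was 0.1 at each time and 0.00025 over the times. The number of miRNAs detected was 747 in infected and 763 in control libraries at 6 h (exact p = 0.7), 671 and 731 at 12 h, and 608 and 691 at 24 h (exact p = 0.1 at both). Depth, the share taken by the most abundant miRNAs and infection therefore moved together in these libraries. Of the 1218 miRNAs, 499 passed the filter on low counts and were tested, 28 of them with a flounder name, 281 named after other species and 190 numbered candidates.

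At 6 h, the miRNAs called higher in infected spleens included miR-146-x and miR-155-x, both known from innate immune responses. The level of miR-146-x rose 2.50-fold, from 37806 ± 20325 to 94536 ± 11239 CPM (counts-per-million values, TMM-scaled; SD, n = 3). That of miR-155-x, which is induced by Toll-like receptor signalling in macrophages, rose 3.10-fold, from 177 ± 37.3 to 548 ± 136 CPM. The largest rise among the called miRNAs was that of miR-29-x, from 30.1 ± 12.1 to 356 ± 101 CPM (log2 fold change 3.56 ± 0.384, SE). Its counterpart miR-29-y, the other entry of the same number, was at 420 ± 20.4 CPM in controls and 439 ± 28.7 CPM in infected spleens and was not called. Levels of miR-221-x rose from 8.16 ± 6.81 to 44.1 ± 13.8 CPM. Calls also went to miR-146-y and 4 numbered candidates (n016-3p, n199-3p, n049-3p and n113-3p), all of which rose.

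By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9 of the 499 miRNAs tested were called at 6 h, all of them higher in infected fish. An unadjusted p under 0.05 was found for 49, where 24.95 would be expected by chance. No miRNA was called lower by this test as fitted, but other settings called some lower. DESeq2 called 20 miRNAs, 15 higher and 5 lower (miR-190-x, miR-99-y, n093-5p, n108-3p and n127-3p), and limma voom 12 higher and 1 lower (n127-3p). By edgeR, n127-3p was called lower with RLE factors, totals only, the strict filter, no robust estimation, family sums, the most abundant miRNA left out or identical entries counted once. The candidate n093-5p was called lower with no filter or in a fit of the compared groups only. Those called lower at 6 h were named after their values were seen. The adjusted p was 4.29e-05 for miR-29-x, 7.19e-05 for n016-3p and n199-3p, 0.00134 for n049-3p, 0.00545 for miR-146-y, 0.0130 for miR-146-x, 0.0322 for miR-155-x and miR-221-x, and 0.0456 for n113-3p (edgeR, Benjamini-Hochberg). The number of calls fell to 5 without infected 6 h replicate 2, 4 without infected replicate 3, 5 without control replicate 1 and 5 without control replicate 2. The calls of miR-29-x, n016-3p, n199-3p and n049-3p held without each library in turn. The call of miR-146-x was lost without each of those 4 libraries (adjusted p up to 0.107, without control replicate 1), and that of miR-146-y without infected replicate 3 (0.0512) or control replicate 2 (0.0637). Those of miR-221-x, n113-3p and miR-155-x were lost without 8, 12 and 14 of the 18 libraries, with an adjusted p of up to 0.218, 0.218 and 0.293 (edgeR). With upper-quartile factors or totals only, miR-155-x lost its call too. The call of miR-221-x was also lost when it was summed with the other miR-221 entries of its arm (log2 fold change 0.03, adjusted p 0.971).

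At 12 h the same 8 miRNAs were higher again (miR-146-x, miR-146-y, miR-155-x, miR-29-x, miR-221-x, n016-3p, n049-3p and n199-3p), where independent lists would share 0.271. The level of miR-29-x rose from 20.6 ± 4.31 to 445 ± 159 CPM (SD, n = 3), that of miR-155-x from 180 ± 29.5 to 716 ± 193 CPM and that of miR-146-x from 54296 ± 9801 to 142289 ± 6825 CPM. Entries of miR-21, a miRNA that rises in activated myeloid cells, rose as well, pol-miR-21-3p with a log2 fold change of 2.97 ± 0.604 (SE) and miR-21-y with 2.11. The abundant product pol-miR-21-5p was at 34577 ± 9224 CPM in controls and 49651 ± 17064 CPM in infected spleens and was not called. Lower levels were found for miR-375-y, a miRNA of endocrine pancreas, which fell from 57.4 ± 17.2 CPM in controls to 14.6 ± 8.56 CPM in infected spleens. Likewise miR-96-x, a member of the sensory cluster of miR-183, fell from 41.1 ± 20.5 to 10.2 ± 3.81 CPM. In the 12 h controls, both stood above the 6 h controls (15.9 ± 2.12 CPM for miR-375-y and 8.78 ± 2.45 CPM for miR-96-x). They also stood above the 24 h controls (14.1 ± 2.0 and 10.3 ± 0.487 CPM).

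The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 19 miRNAs at 12 h, 15 higher and 4 lower, and 70 had an unadjusted p under 0.05. The adjusted p was 1.65e-06 for n199-3p, 1.87e-06 for miR-29-x, 0.00685 for miR-155-x and miR-146-x and 0.00833 for pol-miR-21-3p and miR-6240-x (log2 fold change 4.50 ± 0.898, SE). Among those lower, the adjusted p was 0.0101 for n005-5p (log2 fold change −2.66 ± 0.568) and 0.0130 for miR-375-y and miR-96-x. The split of calls was 14 higher and 8 lower when libraries were scaled by their totals only and 15 and 7 with upper-quartile factors. These settings shifted the median log2 fold change by −0.126 and −0.102. Without control 12 h replicate 3 the number of calls was 12. Among those lost were pol-miR-21-3p, miR-21-y, miR-6240-x and miR-221-x (adjusted p 0.0608, 0.0831, 0.0609 and 0.0852). The calls of miR-375-y and miR-96-x were lost without infected replicate 1 (0.0811 and 0.0826), infected replicate 3 (0.0764 and 0.0947) or control replicate 1 (0.0521 and 0.0933). That of n005-5p was lost without infected replicate 2 (0.0602) or 3 (0.0606). That of miR-221-x was lost without infected replicate 1 (0.0637) or control replicate 2 (0.0546), and that of miR-21-y without infected replicate 2 (0.0602), control replicate 1 (0.0533) or control replicate 2 (0.0531).

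At 24 h, miR-146-x, pol-miR-21-5p, miR-155-x and miR-223-y were called higher in infected spleens, and miR-142-x and miR-125-x lower. The level of miR-146-x rose from 44784 ± 2858 to 308141 ± 51287 CPM, 6.88-fold, and that of pol-miR-21-5p from 33176 ± 3855 to 105892 ± 29332 CPM, 3.19-fold (SD, n = 3). That of miR-155-x rose from 165 ± 50.5 to 687 ± 349 CPM. The granulocyte miRNA miR-223-y rose from 705 ± 111 to 1661 ± 144 CPM. The level of miR-142-x, which is found in all blood cell lineages, fell from 22209 ± 7004 to 13303 ± 1871 CPM. Again higher, miR-29-x was at 20.9 ± 7.10 CPM in controls and 394 ± 121 CPM in infected spleens, and miR-221-x at 3.67 ± 1.68 and 45.9 ± 23.3 CPM. The exocrine pancreas miRNA miR-216-x fell from 634 ± 363 to 94.7 ± 55.0 CPM.

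**Figure D1:**
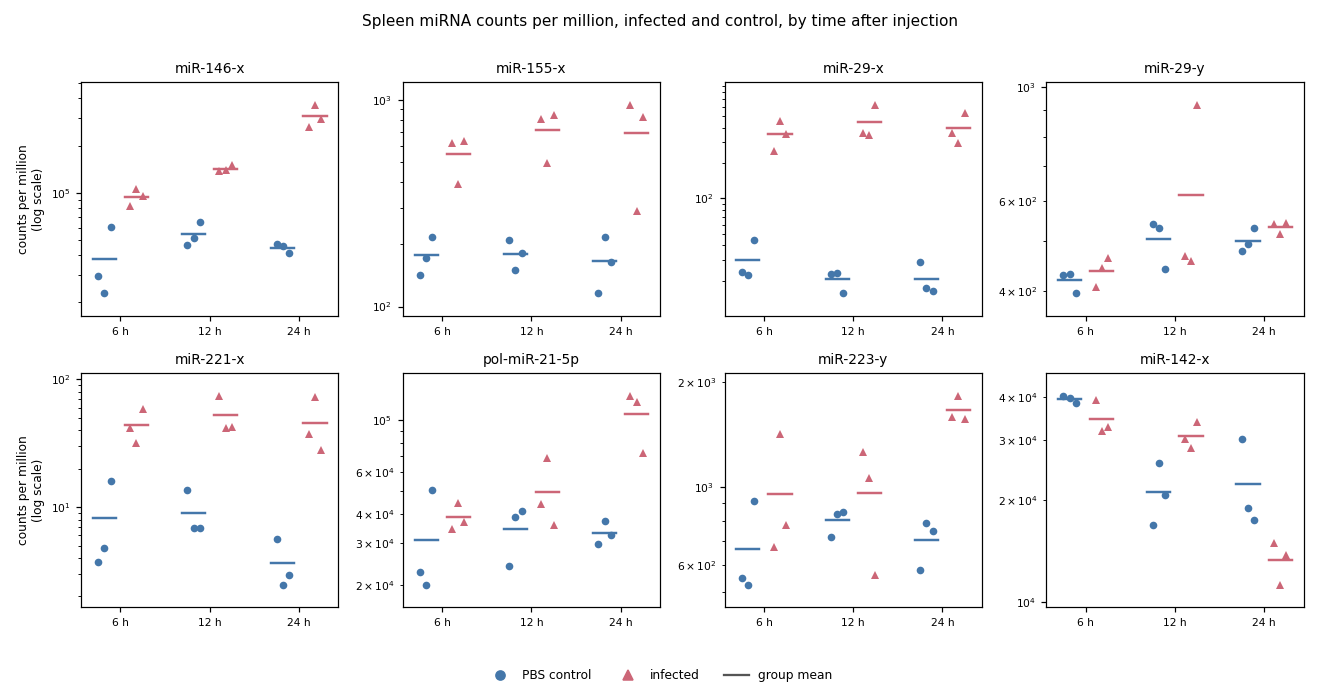
Level of 8 miRNAs in each of the 18 libraries, in TMM-scaled CPM on a log axis, against hours after injection. Circles are PBS-injected controls, triangles infected fish, and each bar is the mean of the 3 libraries of a group. miR-29-x lies near 20 to 30 CPM in the controls and near 356 to 445 CPM on average in infected fish, and miR-29-y was at similar levels in both.

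Some miRNAs that are rare in controls reached high counts at 24 h. For miR-6240-x there were counts of 2325, 4338 and 16217 in the 3 infected libraries and of 10, 75 and 70 in the controls. Counts of miR-11987-x were 267, 1240 and 1605 against 0, 9 and 5, and those of miR-1335-y were 85, 209 and 897 against 5, 7 and 19. Among the miRNAs that fell, miR-455-y went from 927 ± 102 to 507 ± 16.9 CPM (SD, n = 3). Levels of miR-338-x fell from 12.2 ± 6.82 to 3.60 ± 1.06 CPM and those of miR-204-y from 2.63 ± 1.24 to 0.458 ± 0.143 CPM. Both miR-1338-x (log2 fold change −1.68) and miR-1388-x (−1.67) also fell. The log2-transformed counts of this pair had a Pearson r of 0.999993 over the 18 libraries. The median over libraries of the ratio of miR-1338-x to miR-1388-x was 0.963. The values of each are therefore uncertain where reads were shared. Of the abundant miRNAs, miR-125-x fell (log2 fold change −0.61 ± 0.173, SE). Not called were miR-26-x, miR-143-y, miR-126-y, miR-100-x, miR-181-x, pol-miR-144-3p and miR-451-x, with log2 fold changes of 0.02, −0.03, 0.01, −0.21, −0.08, 0.30 and 0.25.

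**Figure D2:**
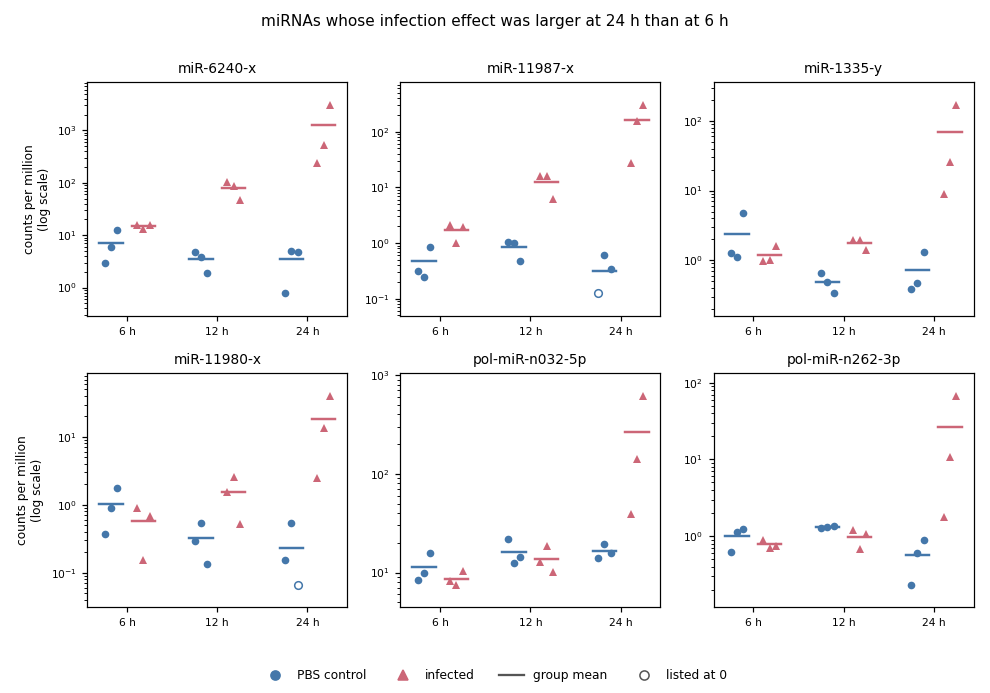
Level of 6 miRNAs with larger infection effects at 24 h than at 6 h, in TMM-scaled CPM on a log axis, in each of the 18 libraries against hours after injection. Circles are controls, triangles infected fish, bars group means, and hollow symbols stand for libraries in which the miRNA is listed at 0. The 3 infected 24 h libraries hold 2325 to 16217 counts of miR-6240-x, and the 24 h controls 10 to 75.

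By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 48 miRNAs were called at 24 h, 30 higher and 18 lower, 17 of them numbered candidates. In all, 97 had an unadjusted p under 0.05. The adjusted p was 3.47e-06 for miR-29-x, 6.15e-06 for miR-146-x, 2.72e-05 for miR-11987-x, 6.80e-05 for miR-6240-x and 0.000507 for miR-1335-y. It was 0.000815 for miR-221-x, 0.00214 for miR-155-x, 0.00472 for pol-miR-21-5p and 0.0160 for miR-223-y. Of those lower it was 0.00490 for miR-455-y, 0.00906 for miR-204-y, 0.00916 for miR-338-x, 0.0138 for miR-216-x, 0.0257 for miR-142-x and 0.0314 for miR-125-x (edgeR). The balance of the calls depended on the scaling, with 24 higher and 26 lower under upper-quartile factors, and 25 higher and 65 lower with libraries scaled by their totals only. These settings shifted the median log2 fold change by −0.225 and −0.389. Under either of them miR-223-y was not called (adjusted p 0.0580 and 0.102), and with totals only miR-126-y was called lower (log2 fold change −0.399). By limma voom miR-204-y was not called (adjusted p 0.151).

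Without infected 24 h replicate 3, the shallowest library, the number of calls at 24 h was 30. There, miR-6240-x and miR-1335-y had log2 fold changes of 6.74 and 4.54 in place of 8.51 and 6.55. Of the 48 calls, 26 held without each library in turn, those of miR-29-x, miR-146-x, miR-155-x, miR-221-x and pol-miR-21-5p among them. The calls of miR-216-x, miR-142-x and miR-125-x were lost by edgeR without infected replicate 2 (adjusted p 0.0837, 0.171 and 0.162), infected replicate 3 (0.0759, 0.0794 and 0.0868) or control replicate 1 (0.0801, 0.18 and 0.183). The call of miR-223-y was lost without infected replicate 2 (0.0838), infected replicate 3 (0.0708) or any of the 3 controls (0.107, 0.0548 and 0.0835). That of miR-338-x was lost without infected replicate 2 (0.0699) or control replicate 1 (0.0646), and those of miR-1338-x and miR-1388-x without infected replicate 3 (0.0832). That of miR-221-x was lost when summed with the other miR-221 entries of its arm (log2 fold change 0.23, adjusted p 0.525).

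Averaged over the 3 times, 39 miRNAs differed between infected and control spleens, 32 higher and 7 lower (edgeR quasi-likelihood, Benjamini-Hochberg). miR-29-x had the smallest adjusted p (log2 fold change 4.08 ± 0.227 SE, adjusted p 1.89e-09), and miR-146-x (1.83 ± 0.157, adjusted p 4.49e-07) and miR-155-x (1.89 ± 0.219, adjusted p 9.87e-06) were among the next. The 7 lower miRNAs were n127-3p (−1.19), n005-5p (−2.07), miR-338-x (−1.24), n020-3p (−2.50), miR-204-y (−1.35), n075-5p and miR-455-y. For this comparison, the last pair was named after its values were seen. A joint test of the 3 times called 43 miRNAs. The averaged calls were 25 higher and 10 lower with upper-quartile factors and 26 higher and 43 lower with totals only. The joint test gave 28 calls without infected 24 h replicate 3, 23 without control 24 h replicate 1 and 27 without control 24 h replicate 3.

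The effects at the 3 times were compared directly, each time having its own controls. Of the 9 higher at 6 h, 8 were also higher at 12 h and at 24 h, where 0.271 and 0.541 would be expected of independent lists. At both 12 and 24 h, 14 were higher (0.902 expected). The candidate n005-5p was the only miRNA lower at both 12 and 24 h (0.144 expected). Across all 499 miRNAs, which are not independent replicates, the log2 fold changes at 6 and 12 h had a Pearson r of 0.243 (Spearman 0.00739), those at 6 and 24 h 0.192 (0.230) and those at 12 and 24 h 0.229 (0.151).

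By edgeR with TMM factors, the infection effect was called larger at 24 h than at 6 h for 7 miRNAs and smaller for 0. The split was 8 larger and 6 smaller with totals only, which shifted the median difference by −0.264, 7 and 2 with no filter, 10 and 2 in libraries thinned to equal depth, and 13 and 11 by DESeq2. These were miR-6240-x (difference of the log2 fold changes 7.46 ± 1.23, SE), miR-1335-y (7.54 ± 1.29), miR-11987-x (7.11 ± 1.26) and miR-11980-x (7.06 ± 1.51). The others were n262-3p (5.85 ± 1.25), n032-5p (4.41 ± 0.922) and n112-3p (2.57 ± 0.587). Of these, miR-11980-x and n112-3p were named after their values were seen. In the 24 h controls, 1 library of miR-11987-x (counts of 0, 9 and 5) and 1 of miR-11980-x (2, 8 and 0) is listed at 0, so that the size of these differences is uncertain. By edgeR with Benjamini-Hochberg adjustment, the adjusted p was 0.00618 for miR-6240-x and miR-1335-y, 0.00626 for miR-11987-x, 0.0201 for miR-11980-x, n262-3p and n032-5p, and 0.0345 for n112-3p. For miR-146-x the difference was 1.46 ± 0.375 with an adjusted p of 0.0670. For miR-29-x and miR-155-x it was 0.68 ± 0.493 (0.638) and 0.42 ± 0.519 (0.833; edgeR, Benjamini-Hochberg). No miRNA passed the test between 12 and 6 h or between 24 and 12 h by edgeR as fitted, where 66 and 78 had an unadjusted p under 0.05. The smallest adjusted p were 0.0604, for miR-375-y, and 0.0507, for n262-3p. Other edgeR settings called some, 2 and 7 with RLE factors, 3 and 6 with upper-quartile factors and 0 and 9 with totals only. DESeq2 called 17 and 42 and limma voom 1 and 0. The joint test over the 3 times called 7, namely miR-6240-x, miR-11987-x, miR-1335-y, n032-5p, n262-3p, miR-375-y and miR-96-x. In its place limma voom called 0 and DESeq2 49.

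Of the 7 calls between 24 and 6 h, 2 held without each library in turn, and of the 7 of the joint test 0 did. The 7 calls between 24 and 6 h became 3 without infected 6 h replicate 2, infected 6 h replicate 3, infected 24 h replicate 3, control 24 h replicate 1 or control 24 h replicate 3. They became 2 without control 6 h replicate 3 and 12 without infected 24 h replicate 1. Without infected 24 h replicate 3 the difference was 3.79 ± 0.892 (SE) for n262-3p and 2.85 ± 0.622 for n032-5p, neither called. In the same comparison limma voom called 0 and DESeq2 24. The joint test called 0 without infected 6 h replicate 2, control 24 h replicate 1 or control 24 h replicate 3, and 2 without infected 24 h replicate 3. It called 3 without infected 12 h replicate 3, control 12 h replicate 1 or control 12 h replicate 3, and 15 without infected 12 h replicate 2 or infected 24 h replicate 1. Between 12 and 6 h the count was 2, 1, 1, 5, 3 and 2 without infected 6 h replicates 1 and 3, infected 12 h replicates 1 and 2, control 12 h replicate 2 and control 24 h replicate 2. Between 24 and 12 h it was 8, 1, 7, 1 and 12 without control 6 h replicate 3, infected 12 h replicates 1 and 2, control 12 h replicate 2 and infected 24 h replicate 1.

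Among the PBS-injected controls, 22 miRNAs differed between times. The 5 with the smallest p were miR-96-x and miR-183-x of the sensory cluster, the pancreatic miR-375-y and miR-7-x, and miR-25-y. All were higher at 12 h than at 6 h, with log2 differences of 2.23, 2.16, 1.85, 1.55 and 0.63 (adjusted p 0.0223 each; edgeR, Benjamini-Hochberg). The level of miR-7-x was 39.7 ± 7.40 CPM at 6 h, 116 ± 26.8 at 12 h and 105 ± 37.5 at 24 h, and that of miR-25-y 2747 ± 156, 4248 ± 321 and 4743 ± 599 CPM (SD, n = 3). None of the 22 calls held without every library. The count was 7, 13 and 10 without control 6 h replicates 1, 2 and 3, and 0, 9 and 14 without control 12 h replicates 1, 2 and 3. It was 43 and 10 without control 24 h replicates 1 and 3. DESeq2 called 70 miRNAs in this comparison and limma voom 28, and edgeR 14 in libraries thinned to equal depth and 15 in a fit of the controls only.

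**Figure D3:**
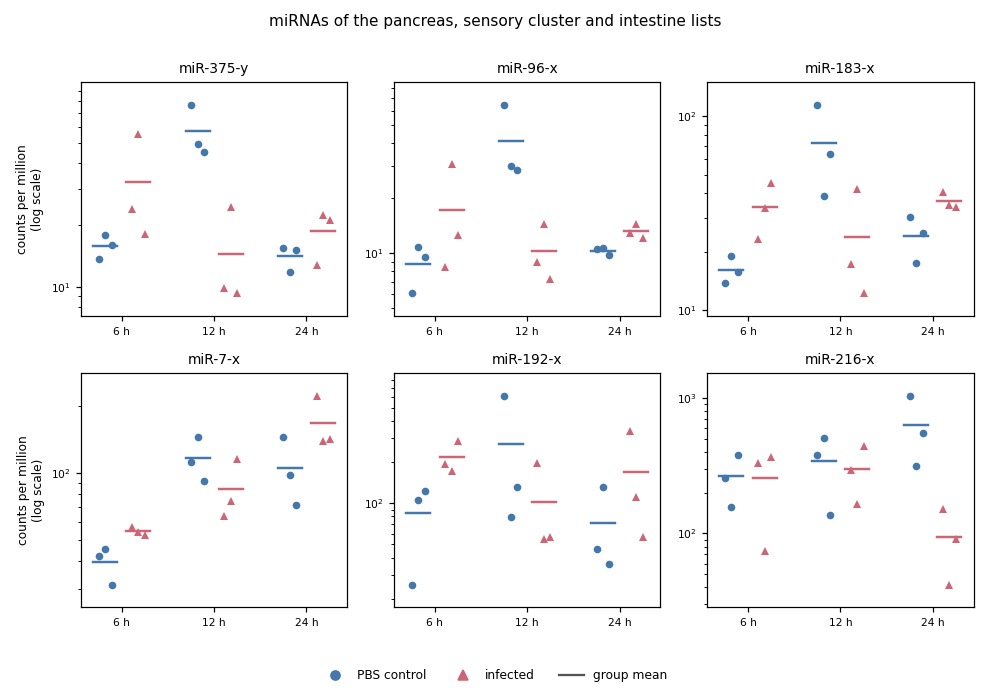
Level of 6 miRNAs on the lists of pancreas, sensory cluster and intestine markers, in TMM-scaled CPM on a log axis, in each of the 18 libraries against hours after injection. Circles are controls, triangles infected fish, and bars group means. The 12 h controls lie at 57.4 CPM on average for miR-375-y and 41.1 CPM for miR-96-x, above the controls of 6 h and 24 h.

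In infected fish, 45 miRNAs differed between times. Those with the smallest p were n032-5p, miR-11987-x, miR-1335-y and miR-6240-x, higher at 24 h than at 6 h by 4.93, 6.58, 5.84 and 6.43 on the log2 scale. Next to them, miR-142-x fell by 1.38 (adjusted p 0.00138 for miR-1335-y and 0.000816 for the others; edgeR, Benjamini-Hochberg). In the controls, miR-142-x was lower at 24 h than at 6 h as well, with a log2 difference of −0.83. The count was 28 without infected 6 h replicate 3, 21 without infected 24 h replicate 2 and 24 without infected 24 h replicate 3.

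Of the lists of miRNAs, the inflammation-responsive list (20 measured members) stood above the other miRNAs at 12 and 24 h by limma's camera test with a preset correlation (adjusted p 0.00264 and 0.00825). With an estimated correlation the adjusted p was 0.637, 0.136 and 0.393 at 6, 12 and 24 h, so that the list passed at no time. It had 5 members higher and 0 lower at 12 h and 9 higher and 2 lower at 24 h. The 5 at 12 h were miR-146-x, miR-146-y, miR-155-x, pol-miR-21-3p and miR-21-y. Those that rose at 24 h included the same 5, pol-miR-21-5p, miR-21-x and miR-223-y. Entries of miR-21 that differ in species name can share reads. The numbers of members are therefore numbers of entries, not of separate miRNA families. Those that fell were miR-125-x and miR-9-y, a neural miRNA also induced by NF-kB (log2 fold change −2.35, adjusted p 0.0386 by edgeR). The call of miR-9-y was lost without 10 of the 18 libraries (adjusted p up to 0.183, without control 24 h replicate 1). At 6 h, 3 members rose (adjusted p of the list 0.0579). Adjusted over the list alone, the counts were 4 higher at 6 h, 5 at 12 h, and 9 higher and 2 lower at 24 h.

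The pan-leukocyte list (9 members, all of them also on other lists) had 3 members higher at 6 h, 3 at 12 h, and 5 higher and 1 lower at 24 h, where the member that fell was miR-142-x. The camera adjusted p was 0.0579, 0.00904 and 0.0402, and 0.573, 0.0926 and 0.393 with an estimated correlation. Adjusted over the list alone, 4, 4 and 5 were higher and, at 24 h, 2 lower. Of the 7 members of miR-221/miR-222, 1 rose at 6 h, 1 at 12 h and 2 at 24 h, and 2, 2 and 3 rose adjusted over the list alone. The camera adjusted p was 0.0502, 0.576 and 0.0498, and 0.573, 0.842 and 0.502 with an estimated correlation. The sensory cluster (4 members) was lower at 12 h (adjusted p 0.00264; 0.134 with an estimated correlation), with 1 member lower, miR-96-x, and 3 adjusted over the list alone. At 6 h its median log2 fold change was 1.03 (adjusted p 0.0502). The list of pancreas markers (7 members) was lower at 12 h (adjusted p 0.0196; 0.0926 with an estimated correlation), with 1 member lower, miR-375-y, and 2 adjusted over the list alone. At 24 h 1 member, miR-216-x, was lower, and 2 adjusted over the list alone. The clusters of miR-17/92 (15 members), whose products promote proliferation, stood below the other miRNAs at 12 h (adjusted p 0.00974; 0.0926 with an estimated correlation). Of their members 0 passed the edgeR test over all miRNAs, with 5 lower adjusted over the list alone.

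Smaller numbers of calls came from other lists. Of the 4 members of the myeloid list, 2 rose and 1 fell at 24 h (1 higher at 6 h, and 2 higher and 2 lower at 24 h, adjusted over the list alone). The lymphoid list had 1 of its 6 members, miR-155-x, higher at each time, and so was 1 of the 2 members of miR-29, miR-29-x. The 1 measured member of miR-34/miR-449, miR-34-x, rose at 24 h (log2 fold change 1.75, adjusted p 0.0408 by edgeR). Its call was lost without 16 of the 18 libraries (up to 0.275, without infected 24 h replicate 3). On the neural list, 1 of the 13 members, miR-9-y, fell. Adjusted over the list alone, 1 of the 8 members of miR-10/100/99 was lower at 6 h and 1 of the 4 of the teleost infection-responsive list at 24 h. No member passed the edgeR test at any time, over all miRNAs, on the lists erythroid (7 members), let-7 (10), miR-15/16 (6), miR-30 (2), miR-10/100/99 (8), miR-181 (2) and hypoxia-responsive (3). The same held for the lists miR-130/miR-301/miR-454 (6), miR-23/24/27 (6), miR-199/miR-214 (6), thrombocyte or endothelial (2), smooth muscle or stroma (10), skeletal or cardiac muscle (5), liver (2), intestine or kidney epithelium (3), epithelium (9) and teleost infection-responsive (4). The miR-430 list had no measured member. The miRNAs miR-462-x and miR-731-x, known to respond to virus infection in teleosts, had log2 fold changes of 0.30 and 0.34 at 6 h, 0.71 and 0.54 at 12 h, and −0.68 and −0.84 at 24 h, none called.

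The camera test called 0 of the 22 lists tested at 6 h (5 at an unadjusted p under 0.05), 5 at 12 h and 3 at 24 h. With an estimated correlation it called 0 at each time, and the fry test called 2, 5 and 4. Without 1 library, the count at 6 h was 4 without infected replicate 1, 1 without control replicate 2 and 3 without control replicate 3. At 12 h it was 3 without infected replicate 2 or control replicate 2. At 24 h it was 0 without infected replicate 1 or control replicate 2 and 1 without infected replicate 3 or control replicate 3. Median, mean and test differed in sign for let-7, miR-15/16, erythroid, lymphoid and pancreas at 6 h. They differed for let-7, hypoxia, miR-221/miR-222, lymphoid and muscle at 12 h, and for miR-17/92, miR-10/100/99 and muscle at 24 h, none of which was called at that time.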

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

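The tests of depth, scaling, 1 library and another RNA source for the 24 h group of miRNAs, those of shared reads and of scaling for miR-29, and that of a fall in infected fish at 12 h were chosen after the result was seen; the tests of different hairpins and of carried-over tissue were set before theirs.

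The infection effect differed between 24 h and 6 h, by a test of the difference itself, for miR-6240-x (7.46 on the log2 scale), miR-11987-x (7.11), miR-1335-y (7.54), miR-11980-x (7.06), pol-miR-n032-5p (4.41), pol-miR-n112-3p (2.57) and pol-miR-n262-3p (5.85). Over the 3 times it differed by the joint test for miR-6240-x, miR-11987-x and miR-1335-y (adjusted p 0.0186 each, edgeR), pol-miR-n032-5p and pol-miR-n262-3p (0.0272 each), miR-375-y (0.0367) and miR-96-x (0.0428). These calls lean on single libraries: the joint test called 0 miRNAs without infected 6 h replicate 2, control 24 h replicate 1 or control 24 h replicate 3. They also depend on the tool: limma voom called 0 in the joint test and 0 between 24 and 6 h, and DESeq2 49 and 24.

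The 7 miRNAs that gained most between 6 and 24 h form the first pattern. The difference between 24 and 6 h stayed called for 7 of them after thinning to equal depth and for 7 with libraries scaled by total counts only, which argues against depth and TMM scaling as the whole cause. Without infected 24 h replicate 3 it stayed called for 3, miR-6240-x (5.74 ± 0.939, SE), miR-1335-y (5.57 ± 0.917) and miR-11987-x (6.27 ± 1.20), which argues against that library alone as the whole cause for these 3. The other 4 lost the call. Their differences became 5.83 ± 1.5 in place of 7.06 ± 1.51 for miR-11980-x (adjusted p 0.103, edgeR), 3.79 ± 0.892 in place of 5.85 ± 1.25 for pol-miR-n262-3p (0.0599), 2.85 ± 0.622 in place of 4.41 ± 0.922 for pol-miR-n032-5p (0.05001) and 2.61 ± 0.603 in place of 2.57 ± 0.587 for pol-miR-n112-3p (0.0599). The first 3 of these differences were smaller, the last was not, and more miRNAs were tested in that fit (533 in place of 499). All 4 lay 3.90 to 4.58 standard errors above 0, where that library as the whole cause would leave them near 0, and all 4 were still called higher at 24 h (adjusted p 0.00459 to 0.0243, edgeR). This argues against that library alone as the whole cause for these 4 too, although their calls between 24 and 6 h were lost without it. RNA of 1 other source counted under these names stays open too: within groups the 7 rose and fell together, with a median pairwise r of 0.784 (0.222 to 0.899), above the upper bound of the 95% range of 1000 random sets (0.230) but below the r over 0.9 that a single source in a fixed ratio was taken to need. In the controls, 61 of 63 values were above 0. A response to infection, the biological explanation that the design offers, and RNA of another source, such as fragments of other RNA classes or of the bacterium, cannot be told apart without sequences. Chance is not excluded for the number of calls between 24 and 6 h either. Of 100 splits of the same libraries into groups of the same sizes, 9, the real one included, gave as many calls.

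The second pattern is miR-29-x, higher in infected fish at each time, while miR-29-y was not called. The log2 ratio of miR-29-x to the candidate n199-3p varied between libraries of a group with an SD of 0.578. This argues against the same reads being counted under both names. It cannot exclude that a part of the reads was shared, since the ratio could then vary too. Scaling is argued against by the ratio of miR-29-x to miR-29-y within a library, which was higher in infected fish by 3.95 on the log2 scale (3.52, 4.18 and 4.15 at 6, 12 and 24 h; exact permutation within times, p = 0.00025, the smallest it allows). Different hairpins under the 2 names stay open: within groups the pair correlated at r = 0.451, between the lower quartile (0.171) and the median (0.533) of 80 such pairs. A change in processing or stability of 1 arm under infection is a hypothesis that was not tested.

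The third pattern is miR-375-y, miR-183-x, miR-96-x and pol-miR-182-5p, with lower values in infected than in control spleens at 12 h, miR-375-y and miR-96-x past the threshold over all miRNAs. The difference came mostly from the controls, which at 12 h lay a median of 1.88 above the other controls on the log2 scale, with infected fish at −0.622 against the other infected; this leaves a fall in infected fish possible in part. Tissue carried into the 12 h control samples stays open. The 4 miRNAs and 3 intestine markers correlated at r = 0.13 within groups over 18 libraries (permutation p = 0.705), with a Spearman rho of 0.0279 (permutation p = 0.925). Without the 2 libraries farthest from the median, infected 12 h replicate 2 and control 12 h replicate 1, r was 0.00495. Control 12 h replicate 1 is also the 12 h control richest in miR-192-x, so leaving it out cannot count against carried-over tissue. The r of 0.13 over 18 libraries lies under the bound of 0.2 set beforehand, and it was first read as excluding the explanation. The reading was changed after r was seen, because the uncertainty of r does not exclude higher values. miR-192-x, an intestine marker, reached 677 CPM (without TMM scaling) in control 12 h replicate 1 against 81.4 and 130 CPM in the other 12 h controls. For miR-375-y the values were 85.5 against 51.3 and 45.2 CPM, and the same library was highest for the other 3 miRNAs. Against the other times, miR-192-x, miR-194-x and miR-215-x were higher in 12 h controls (1.51, 1.64 and 1.66, log2) and lower in 12 h infected fish (−0.962, −1.05 and −0.906). An r within groups leaves out such shifts between groups, so it cannot count against carried-over tissue.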

How the results depend on the processing

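The fits with identical entries counted once, with thinned libraries and without numbered candidates were chosen after the data were seen; the other alternatives were planned. The causes of the changes below were not tested, except where fewer miRNAs or libraries entered a fit. Of 2389 alternative values of the 74 called single miRNA values, 2232 kept direction and call and 157 lost the call. Of 1874 values of uncalled miRNAs, 8 gained a call and 121 changed sign, 1 of them with a call: miR-126-y at 24 h was −0.399 with total count only (0.01 otherwise). Depth limits what can be seen: listed zeros can hide counts under 2, and the shallowest library has 6615484 counts.

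DESeq2 called 20 miRNAs at 6 h, 88 at any time, 17 between 12 and 6 h, 24 between 24 and 6 h, 42 between 24 and 12 h, 49 differing among times, 70 for time in controls and 79 in infected fish. With total count only there were 90 calls at 24 h, 69 averaged, 69 at any time, 14 between 24 and 6 h, 9 between 24 and 12 h, 15 among times and 74 for time in infected fish. RLE factors gave 2 between 12 and 6 h, 7 between 24 and 12 h, 12 among times and 4 lists at 6 h, and upper-quartile factors 3 between 12 and 6 h and 6 between 24 and 12 h. No filter gave 5 between 12 and 6 h, 13 between 24 and 12 h and 17 among times; the strict filter gave 7, 12 and 13, and 4 between 24 and 6 h. limma voom gave 1 between 12 and 6 h, 0 between 24 and 6 h and 0 among times. A fit of the compared groups only gave 1 between 12 and 6 h, 3 between 24 and 6 h, 1 between 24 and 12 h and 25 for time in infected fish. Between 24 and 12 h, no robust estimation gave 6, family sums 9, leaving out the most abundant miRNA 8 and identical entries counted once 8; among times the last 3 gave 15, 11 and 12. Thinning gave 12 between 24 and 6 h, 2 between 24 and 12 h, 12 among times and 14 for time in controls. Without numbered candidates there were 4, 12 and 31 calls at 6, 12 and 24 h, 20 averaged, 27 at any time and 4 between 24 and 12 h. For the lists, fry called 2 at 6 h, and an estimated correlation 0 at 12 h and 0 at 24 h. The top 10 chosen within each library differed in share by 1.18 at 6 h (3.19 otherwise). Among called miRNAs only, r was 0.541, 0.296 and 0.645 for 6 and 12, 6 and 24, and 12 and 24 h, and with a prior count of 2 it was 0.307 and 0.409 for the last pairs.

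Replicate numbers are shared by the groups, but same-numbered libraries did not deviate together: the median r was −0.0206 (−0.244 to 0.294, 45 pairs) against 0.000907 for other pairs, and 6 of 18 libraries correlated best with their own number. With a replicate block, time in controls had 12 calls in place of 22, and no other count of calls moved by over 1.5 times.

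Leaving out each library in turn, calls ranged from 4 to 11 at 6 h, 12 to 21 at 12 h, 30 to 61 at 24 h, 29 to 42 averaged and 23 to 48 at any time. The range was 0 to 5 between 12 and 6 h, 2 to 12 between 24 and 6 h, 0 to 12 between 24 and 12 h, 0 to 15 among times, 0 to 43 for time in controls and 21 to 52 in infected fish, and for the lists 0 to 4, 3 to 6 and 0 to 2. Infected minus control totals ranged from −3.28 to −2.19, −3.78 to −3.03 and −4.82 to −2.28 mega-counts at 6, 12 and 24 h, and top 10 shares from 2.43 to 3.90, 2.13 to 3.26 and 8.51 to 10.1 points. Shares of miR-146-x ranged from 4.79 to 7.16, 7.62 to 8.40 and 18.0 to 20.01 points, and miRNAs detected from −46.3 to 10.7, −76.3 to −44.7 and −109.7 to −58.2.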

Other observations

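The tests of other splits were all set before their results were seen. Markers of other tissues varied between the 12 h controls, given here in CPM without TMM scaling. The liver miRNA pol-miR-122-5p was at 784, 47.3 and 77.5 CPM in control replicates 1, 2 and 3. In the same order, miR-194-x, of intestine or kidney, was at 52.9, 7.61 and 9.75 CPM. The pancreatic miR-217-x was at 351, 338 and 153 CPM in the same libraries. Against the mean of the 6 and 24 h controls, miR-192-x, miR-194-x and miR-215-x were higher at 12 h by 1.51, 1.64 and 1.66 on the log2 scale, pol-miR-122-5p by 0.746 and miR-217-x by 0.628, while the exocrine pancreas miRNA miR-216-x was lower (−0.341). None of the intestine or liver markers was called between infected and control fish at any time.

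Other splits of the same libraries into groups of the same sizes were fitted for each count of calls. For infection at 6, 12 and 24 h the real counts of 9, 19 and 48 stood against a highest of 0 in the other splits at each time, and 1 of 10 splits, the real one, reached the count; 10 splits are too few for a share under 0.05. The same limit holds for the list tests at 12 and 24 h, where 2 and 1 of 10 splits gave as many lists as the real 5 and 3, and the highest of the others was 6 and 2. At 6 h the real count of lists was 0, which each of the 10 splits reaches by definition, so that the splits test nothing there (highest other 5). Over 100 splits drawn within times, chance was excluded for the averaged effect (1 of 100, 39 calls against a highest other of 10). It was also excluded for infection at any time (1 of 100, 43 against 19). For the joint test of time dependence, 3 of 100 splits reached the real count (7 against 22). These splits exchange infected and control libraries, which removes the infection effect itself and not only its change over time. They therefore cannot decide whether that count is due to chance. Nor was chance excluded for the difference between 24 and 6 h (9 of 100, 7 against 36), where the same limit holds. Between 12 and 6 h and between 24 and 12 h the real count was 0, which 100 of 100 splits reach by definition, so that the splits test nothing there (highest other 19 and 24). The highest splits for the differences between 24 and 6 h (36 calls) and between 12 and 6 h (19) exchange all 3 infected libraries at 6 h with the controls and 0 at the other time, so that infection effects add up in place of being subtracted, a structure of the samples. That for the joint test of time dependence (22) exchanges all 3 at 6 h and 1 at 12 h, and that for the difference between 24 and 12 h (24) exchanges 2 at 12 h and 0 at 24 h. For time in controls 1 of 100 splits, the real one, reached the count (22 against a highest other of 17). Chance was excluded there only for the count as fitted. Without control 12 h replicate 1 that count was 0, and 0 of the 22 calls held without each library in turn. For time in infected fish, 3 of 100 splits reached the real count (45 against a highest other of 54). With 100 drawn splits, that share is not clearly under 0.05, so chance is not firmly excluded there.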
